A study of Homo sapiens with 39 samples.

How the data were processed

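Abundance of single-guide RNAs was measured by sequencing in pooled CRISPR knockout screens of A375, a melanoma cell line with an activating BRAF mutation, in cells that already lacked MED12 or MED23, subunits of the Mediator coactivator complex. An epigenetic library of 12214 guides was screened in MED12 knockout and in MED23 knockout cells, and a whole-genome library of 77441 guides was screened in MED12 knockout cells. Cells were sampled at day 0 and after growth in DMSO or in vemurafenib, an inhibitor of mutant BRAF, at 2 µM for MED12 knockout cells (days 8 and 14) and 1 µM for MED23 knockout cells (day 14). The 13 groups held 3 libraries each, 39 in all. Guide sequences were amplified from genomic DNA by PCR, and no molecular identifiers are mentioned in the labels, so reads are not independent molecules and counting error alone understates the spread.

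The authors deposited raw read counts per guide and library in 3 tables, 1 per screen, with no normalization. Demultiplexing was done with bcl2fastq, alignment with HISAT2 and counting with HTSeq, per the submitters' processing notes. Versions, the reference of guide sequences and any filter on reads are not given in the sources used here. Every value in the tables was checked to be a whole number of 0 or more, and 0 columns lacked a sample label. Guide names carry a gene symbol and a guide number. Of 1115 symbols in the epigenetic library 1069 are current symbols and 43 are an older name of 1 gene in the RefSeq gene table, and of 19113 symbols in the whole-genome library 18221 are current and 808 are older names. Symbols are printed as the tables give them. No coordinates were used. The epigenetic library also held control guides named CTRL (83), AAVS1 (267, aimed at a safe-harbour locus) and Zhang (714), and the whole-genome library held 1000 guides without a named target.

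Counts per guide were tested in R 4.3.3 with edgeR 4.0.16. Guides were kept by filterByExpr (minimum count 10, minimum total count 15), which kept 12214 of 12214 guides in each epigenetic screen and 77158 of 77441 in the whole-genome screen. Libraries were scaled with TMM, a quasi-likelihood model with 1 mean per group was fitted to all libraries of a table, and contrasts were tested 2-sided. Guides that target genes were then ranked by signed p in each direction, and the ranks of each gene were combined by robust rank aggregation (RRA, alpha 0.25) against a null of 10000000 seeded uniform draws for the same number of guides. The gene p is 2 times the smaller of the p values of both directions and was adjusted by Benjamini-Hochberg over all genes with at least 3 tested guides (1115 genes with 10 guides each in the epigenetic library, 19101 genes with mostly 4 in the whole-genome library), with a threshold of 0.05. The number of draws was raised after the initial counts of genes had been seen, since fewer draws limited the smallest p. Adjusted p values from these steps are written edgeR/RRA adjusted p. Effects are given as the median over guides of the log2 fold change, and as the change in gene score, the mean over tested guides of log2 CPM (counts scaled by library size with TMM, with 0.5 added), with its standard error from the 3 libraries of each group. Summed CPM over the guides of a gene are given with the SD of 3 libraries. The labels do not say whether replicates of a group were infected or cultured separately, so they may be technical.

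Contrasts were vemurafenib against DMSO at the same day, DMSO at day 14 against day 0 (written growth), the difference of the vemurafenib effects between days 14 and 8, and the difference of the day-14 vemurafenib effects between MED12 and MED23 knockout cells in 1 fit to the day-0 and day-14 libraries of both epigenetic screens. Contrasts of vemurafenib at day 14 against day 0, and the same difference between knockouts for growth, were added after the data had been seen. Genes were named by this rule: up to 10 enriched and up to 10 depleted genes with the lowest adjusted p among those past the threshold whose 3 treated libraries all lay on 1 side of the 3 control libraries, which chance gives for 10% of genes that do not differ. Where none passed, the 3 with the lowest p were named as not passing. Members of the gene lists that passed could be named as well, MED12, MED23, BRAF, NF1 and NF2 always, and up to 10 genes per difference between effects. Genes named outside this rule are marked where they appear.

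A fixed collection of 43 gene lists, covering chromatin complexes, MAPK and growth-factor signalling, cell-cycle brakes and core essential machines, was tested with camera from limma 3.58.1 on the gene scores, with a preset inter-gene correlation of 0.01 and again with an estimated one, for lists with 5 or more measured genes. The tests were 2-sided and adjusted over the lists within a contrast. Counts of list members past the threshold are given over all genes and adjusted over the list alone. Depletion of core essential genes was the median gene score of the ribosome, proteasome, spliceosome, RNA polymerase and replication lists minus that of the other genes in each library, compared between groups by a 2-sided exact permutation test, which cannot go below p = 0.1 for 3 libraries against 3. Effects in the 2 libraries of MED12 knockout cells were compared across shared genes by Spearman and Pearson correlation with a bootstrap interval from 1000 draws. Overlaps of genes were tested by Fisher's exact test. Between those 2 libraries it was tested in the direction of more sharing only, and elsewhere 2-sided unless stated. Lists, groups, contrasts, tests and the alternatives listed below, apart from those marked as later, were fixed before the data were examined.

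Libraries held 1.64e+07 to 2.08e+07 reads in the epigenetic screen of MED12 knockout cells, 2.28e+07 to 2.90e+07 in that of MED23 knockout cells and 4.78e+07 to 8.76e+07 in the whole-genome screen. The median count per guide ranged from 684 to 1432.5, from 740 to 1879 and from 110 to 797. Replicates differed by far more than counting error: the chi-square per guide between replicates of a group ranged from 19.2 to 1145 over 39 pairs. The common dispersion of guides was 0.347 in the epigenetic screen of MED12 knockout cells, 0.144 in that of MED23 knockout cells and 1.09 in the whole-genome screen. The steps were tested on simulated data: counts of each table were drawn from its mean per guide, dispersions and library sizes, with known changes put into some genes at day 14 of vemurafenib. With 1115 genes, 76% of the 2-fold and 100% of the 4-fold changes were recovered for MED12 knockout cells, and 98% and 100% for MED23 knockout cells, with 0 unchanged genes called by edgeR/RRA in both. With 19091 whole-genome genes, 0% of 2-fold, 10% of 4-fold, 82% of 8-fold and 90% of 16-fold changes were recovered, with 4 unchanged genes called, and the fold sizes 8 and 16 were added after the recovery at 4 had been seen. The list test called 3 of 3 shifted lists and 0 of the unshifted among 30 lists in each simulation.

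Replicate numbers were checked for pairing, since the same number can stand for the same culture across groups. After removing group means, libraries of different groups with the same number correlated at r = 0.332 to 0.899 in the epigenetic screen of MED12 knockout cells (r = -0.487 to -0.150 for different numbers) and at r = 0.458 to 0.919 in the whole-genome screen (r = -0.483 to -0.212). A fit with the replicate number as a block was therefore set beside the unblocked fit in both MED12 screens. It lowered the common dispersion from 0.347 to 0.170 and from 1.09 to 0.496. The simulated data held no pairing and used dispersions without the block, so their recovery describes the unblocked fit only.

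Alternatives were median-ratio size factors (as in DESeq2) or scaling on control guides in place of TMM, no filter on low counts, the replicate block, the DESeq2 1.42.0 Wald test for the guide ranks, guide counts summed per gene and tested with edgeR without rank aggregation, a fit to the libraries of the compared groups only, the estimated correlation and the removal of core essential lists in the list test, the mean in place of the median, and leaving out each library in turn. Alternatives chosen after the data had been seen were removal of the 50 guides with most vemurafenib reads in MED23 knockout cells, gene sums with the replicate block in the whole-genome screen, the replicate block in the list test and gene scores in the comparison of libraries. Scaling on control guides used CTRL and AAVS1 guides in the epigenetic library, without the Zhang guides. In the whole-genome library it used the guides without a named target. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Raw reads were not analysed here, and control guides were left out of the gene ranks because they share no target gene.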

Results

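The parental knockouts, MED12 and MED23, encode subunits of Mediator, which links transcription factors to RNA polymerase. In MED12 knockout cells guides against MED12 did not pass in any contrast. Their median log2 fold change over 10 guides was -0.18 for vemurafenib against DMSO at day 8 and -0.24 at day 14, and -0.01 for growth over 14 days in DMSO (edgeR/RRA adjusted p = 0.513, 1 and 0.679). In MED23 knockout cells the same guides rose under vemurafenib by a median log2 of 5.34 (gene score change 5.32 ± 0.33, SE, n = 3 libraries per group, edgeR/RRA adjusted p = 1.72e-05). MED23 was not a target in the epigenetic library, and in the whole-genome screen of MED12 knockout cells its guides did not pass at day 14 of vemurafenib (median log2 fold change 0.13, gene score change -0.01 ± 0.38, edgeR/RRA adjusted p = 1). BRAF, the kinase that vemurafenib inhibits, rose under the drug in MED23 knockout cells (2.29 ± 0.21, edgeR/RRA adjusted p = 0.0146). It had fallen there during growth in DMSO (-3.24 ± 0.17, edgeR/RRA adjusted p = 0.00587). BRAF did not pass at day 14 of vemurafenib in MED12 knockout cells (0.60 ± 0.26, edgeR/RRA adjusted p = 0.33). NF1, a brake on RAS, rose in both knockouts. NF2, a tumour suppressor of the Hippo pathway, rose under vemurafenib in MED23 knockout cells (2.76 ± 0.14, edgeR/RRA adjusted p = 0.00226, range over the alternatives 0.000155 to 0.45, past the threshold in 11 of 15) but did not pass in MED12 knockout cells (0.56 ± 0.14, adjusted p = 0.3). Guide counts do not measure whether the parental gene was lost, which was not analysed here.

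In MED12 knockout cells at day 14 NF1 rose under vemurafenib from 455 ± 41.8 to 3203 ± 1302 summed CPM (SD, n = 3 libraries each), a gene score change of 2.44 ± 0.38 (SE). SETDB1, a histone methyltransferase of silent chromatin, rose by 1.80 ± 0.17, from 1764 ± 159.8 to 5359 ± 1356 CPM. TP53BP1, a DNA-damage scaffold, rose by 1.24 ± 0.21, and SMAD4, the shared transducer of TGF-beta signals, by 1.15 ± 0.20 (edgeR/RRA adjusted p = 4.46e-05 for these 4 genes). SMARCD1, a subunit of BAF chromatin remodellers, rose by 0.95 ± 0.14 (edgeR/RRA adjusted p = 0.000223), and METTL3, the RNA adenosine methyltransferase, by 0.79 ± 0.12 (adjusted p = 0.000765). MAP3K1, a kinase upstream of JNK, rose by 0.74 ± 0.21 (edgeR/RRA adjusted p = 0.0229). POLE4, a subunit of DNA polymerase epsilon, rose by 0.67 ± 0.16 (edgeR/RRA adjusted p = 0.0229, and 0.123 with the replicate block, range over the alternatives 0.0229 to 0.652). Guides fell for KDM1A, the lysine demethylase LSD1 (-0.89 ± 0.18, edgeR/RRA adjusted p = 0.0123). They also fell for CDK2, a driver of S phase (-0.66 ± 0.08, edgeR/RRA adjusted p = 0.0241, range 0.0163 to 0.239), and for BPTF, the reader subunit of the NURF remodeller (-0.96 ± 0.33, adjusted p = 0.0325, range 0.000268 to 0.911). The receptor kinase ERBB2 also fell (-0.58 ± 0.11, edgeR/RRA adjusted p = 0.0238, and 0.0903 with the block, range 0.0203 to 0.612). So did ARID2 of the PBAF remodeller (-0.45 ± 0.16, edgeR/RRA adjusted p = 0.0372, and 0.0643 with the block, range 0.0112 to 0.872). In all, 10 genes rose and 6 fell, against 79 genes at an unadjusted p under 0.05 where 55.8 were expected by chance. Leaving out vemurafenib library 1 at day 14 left 6 genes enriched, and depleted genes fell to 2 without DMSO library 1 or vemurafenib library 1 and to 3 without any other library.

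Among fixed lists at day 14 in MED12 knockout cells, genes whose loss has been tied to BRAF-inhibitor resistance shifted up (17 measured, 1 rose, 6 when adjusted over the list alone, median log2 fold change 0.28). The shift passed with the preset correlation only (camera adjusted p = 0.00633, and adjusted p = 0.0797 with an estimated correlation). NF1 carried the call over all genes, and CUL3, NF2, SUPT20H, TADA1 and TADA2B joined it over the list alone. CUL3, the scaffold of a ubiquitin ligase, did not pass over all genes (median 0.74, edgeR/RRA adjusted p = 0.38). Neither did TADA2B, an adaptor in the SAGA coactivator (median 0.95, edgeR/RRA adjusted p = 0.151). Checkpoint and cell-cycle brakes also shifted up (15 measured, 2 rose, TP53BP1 among them, the same over the list alone, median 0.27, camera adjusted p = 0.0384, and adjusted p = 0.132 with an estimated correlation). SAGA and ATAC acetyltransferase subunits did so without a single member past the threshold over all genes (26 measured, 2 over the list alone, SUPT20H and TADA2B, median 0.16, camera adjusted p = 0.0384, and adjusted p = 0.132 with an estimated correlation). Silencing factors of histone H3 lysine methylation rose as a list with SETDB1 as the member that passed (14 measured, 1 over the list alone, median 0.13, camera adjusted p = 0.0384, and adjusted p = 0.228 with an estimated correlation). The 4 calls were not held by every set of libraries: 1 list was called without DMSO library 1, vemurafenib library 1 or vemurafenib library 3, and camera called 0 without DMSO library 2 or vemurafenib library 2.

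At day 8 of vemurafenib in MED12 knockout cells NF1 had risen by 1.09 ± 0.22, SETDB1 by 0.94 ± 0.11, TP53BP1 by 0.50 ± 0.13 and SMAD4 by 0.47 ± 0.09 (edgeR/RRA adjusted p = 4.46e-05 for each). TRIM28, the corepressor that recruits SETDB1 to zinc-finger proteins, rose by 0.36 ± 0.06 (edgeR/RRA adjusted p = 0.029) and METTL3 by 0.46 ± 0.10 (adjusted p = 0.00194). SMARCD1 rose by 0.44 ± 0.07 (edgeR/RRA adjusted p = 0.0023) and BRAF by 0.37 ± 0.09 (adjusted p = 0.0442, range over the alternatives 0.00364 to 0.999, past the threshold in 5 of 13). METTL17, a mitochondrial ribosome assembly factor, rose by 0.27 ± 0.13, a call lost with the block (edgeR/RRA adjusted p = 0.00756, and 0.361 with the block, range 0.00756 to 0.999). Guides fell for SMARCC1, a core BAF subunit (-0.41 ± 0.14, edgeR/RRA adjusted p = 0.0013), for the receptor kinase EGFR (-0.48 ± 0.18, adjusted p = 0.0128), and for CDK2 (-0.33 ± 0.03) and the N-terminal methyltransferase NTMT1 (-0.30 ± 0.04, adjusted p = 0.0225 for both). KMT2D, a histone methyltransferase of enhancers (-0.46 ± 0.07, edgeR/RRA adjusted p = 0.0171), and MEN1, a cofactor of its family (-0.45 ± 0.07, adjusted p = 0.0407), fell too. Altogether 12 genes rose and 7 fell (16 and 17 with the replicate block), against 106 at an unadjusted p under 0.05 with 55.8 expected. Enriched genes numbered 6 without DMSO library 1 or 2 and 7 without vemurafenib library 1, and depleted genes 1 without DMSO library 1, 3 without DMSO library 2 or 3 and 4 without vemurafenib library 1. Of the enriched genes, 8 were shared by the days, whose libraries paired by number. CDK2 was depleted at both.

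Lists at day 8 pointed to the same resistance genes in MED12 knockout cells (17 measured, 1 rose, 4 over the list alone, namely CUL3, NF1, TADA1 and TADA2B, median 0.09, camera adjusted p = 0.00335, and adjusted p = 0.0606 with an estimated correlation). MLL methyltransferase subunits shifted down, with KDM6A, KMT2D and MEN1 past the threshold (3 of 20, 3 over the list alone, median -0.07, camera adjusted p = 0.0151, and adjusted p = 0.065 with an estimated correlation). Receptor kinases and the PI3K and mTOR pathway also shifted down (1 of 19 fell, EGFR, and 2 over the list alone with ERBB2, median -0.09, camera adjusted p = 0.0121, and adjusted p = 0.065 with an estimated correlation). Silencing factors rose with SETDB1 and TRIM28 (2 of 14, median 0.05, camera adjusted p = 0.0151, and adjusted p = 0.195 with an estimated correlation). SAGA and ATAC subunits shifted up with TADA1 passing over the list alone (median 0.04, camera adjusted p = 0.0261, and adjusted p = 0.0743 with an estimated correlation). Ribosomal proteins and spliceosome factors shifted up with no member past the threshold (medians 0.09 and 0.17, camera adjusted p = 0.0151 for both, and adjusted p = 0.246 and 0.0655 with an estimated correlation). Core essential genes had fallen from day 0 relative to other genes in both arms (gene score -0.65 in DMSO and -0.58 in vemurafenib). These 2 shifts against DMSO therefore do not show a gain from day 0. BAF and PBAF remodellers passed only with the block (camera adjusted p = 0.0649, and 0.0478 with the block). Of the 7 lists 2 were left without DMSO library 1, and camera called 0 without DMSO library 2 or vemurafenib library 3.

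The enrichment of guides widened between days 8 and 14 of vemurafenib in MED12 knockout cells, where drug effects at both days were compared in 1 fit. NF1 gained 1.37 ± 0.20 in log2 (mean ± SE over 10 guides), SMAD4 0.80 ± 0.09, TP53BP1 0.75 ± 0.07, SETDB1 0.69 ± 0.08 and METTL3 0.53 ± 0.30. The adjusted p from edgeR/RRA was 7.43e-05 for NF1 and TP53BP1, 0.00156 for SMAD4, 0.0293 for METTL3 and 0.035 for SETDB1. Over the alternatives METTL3 and SETDB1 each passed in 8 of 19 (edgeR/RRA adjusted p ranges 0.00517 to 1 and 0.00125 to 1). In all 6 genes changed, each in the direction of the drug, and 12 passed with the replicate block. The count was 3 without DMSO library 1 at day 14. Checkpoint and cell-cycle brakes shifted the same way (median difference 0.14, 2 rose, TP53BP1 among them, 5 rose and 1 fell over the list alone). Their camera adjusted p was 0.025, and the adjusted p = 0.138 with an estimated correlation. So did the resistance genes (0.21, 1 rose, NF1, camera adjusted p = 0.0397, and adjusted p = 0.138 with an estimated correlation).

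Vemurafenib selected far larger changes in MED23 knockout cells, led by CUL3, whose summed guides rose from 1504 ± 156 to 386860 ± 137450 CPM (gene score change 6.79 ± 0.24). A single CUL3 guide held 6.61% to 15.2% of the reads of the vemurafenib libraries. TADA2B, TADA1, CCDC101, TAF6L and TAF5L, all subunits of the SAGA coactivator, rose by 5.74 ± 0.35, 4.08 ± 0.28, 4.26 ± 0.19, 3.06 ± 0.19 and 2.75 ± 0.19. NF1 rose by 4.95 ± 0.10, from 468 ± 19.7 to 28285 ± 12487 CPM, and MED12 from 275 ± 72.7 to 25573 ± 12337. KEAP1, the CUL3 adaptor that holds the antioxidant factor NRF2 in check, rose by 2.86 ± 0.14 (edgeR/RRA adjusted p = 1.72e-05 for these 9 genes). MED19 of the Mediator core rose by 2.45 ± 0.43 (edgeR/RRA adjusted p = 2.79e-05), and CDK8, the kinase of the module that MED12 activates, by 1.43 ± 0.13 (adjusted p = 0.000459). MAP2K1, the kinase below BRAF, rose as well (median 2.59, edgeR/RRA adjusted p = 6.56e-05), and stood at a median of -0.37 against day 0. Guides fell for FBXO11, an adaptor that marks proteins for destruction (-1.02 ± 0.10), for the histone demethylase KDM6A (-0.62 ± 0.08) and for the growth-factor receptor FGFR1 (-0.50 ± 0.17, edgeR/RRA adjusted p = 1.72e-05 for each). EGFR (-0.64 ± 0.07, edgeR/RRA adjusted p = 2.79e-05), the kinase SRC (-0.87 ± 0.14, adjusted p = 6.69e-05), and the corepressor NCOR1 (-0.90 ± 0.13, adjusted p = 0.000149) also fell. Its partner HDAC3 did too (-0.69 ± 0.15, edgeR/RRA adjusted p = 0.000163). DYRK1A, a kinase that favours cell-cycle exit (-0.62 ± 0.10), the mitotic histone kinase GSG2 (-0.70 ± 0.15) and RFWD2, a ubiquitin ligase of ETS factors (-0.51 ± 0.21), fell as well (edgeR/RRA adjusted p = 0.000161, 0.000231 and 0.000663). Summed RFWD2 reads did not fall (801 ± 593 against 766 ± 146 CPM). In total 86 genes rose and 31 fell, against 220 at an unadjusted p under 0.05 with 55.8 expected, and 70 to 91 rose when any library was left out. These changes were against DMSO: against day 0, 26 of the 86 genes that rose were enriched and 15 depleted. Of the 31 that fell, 4 were depleted against day 0 (3.17 expected for independent lists). Growth in DMSO had enriched 5 of the 31 (1.72 expected).

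Among lists in MED23 knockout cells, SAGA and ATAC subunits rose under vemurafenib (14 of 26, 17 up and 1 down over the list alone, median 1.11, camera adjusted p = 3.5e-08, and adjusted p = 0.0172 with an estimated correlation). Examples beyond those above were TRRAP, the scaffold (2.81), TADA3 (2.37), the deubiquitinase USP22 (1.82) and its anchor ATXN7 (1.80, medians). Against day 0 ATXN7 was enriched (1.03), while TRRAP (-0.62), TADA3 (0.45) and USP22 (0.44, medians) were not. The resistance genes, which share members with SAGA, rose too (11 up and 1 down of 17, the same over the list alone, median 2.83, camera adjusted p = 2.51e-06, and adjusted p = 0.0267 with an estimated correlation). TSC1, a brake on mTOR, was the member that fell (-0.44). Ribosomal proteins rose (4 of 37, 5 over the list alone, median 0.98, camera adjusted p = 1.8e-08, and adjusted p = 0.0559 with an estimated correlation), among them RPL5 (1.61). Spliceosome factors (3 of 15, 6 over the list alone, median 1.03, for example SF3B3) and proteasome subunits (3 of 10, 5 over the list alone, median 1.13, for example PSMB3) moved the same way. RNA polymerase subunits did so without a member past all genes (median 0.61). For the spliceosome, proteasome and polymerases the camera adjusted p values were 0.000184, 0.000938 and 0.000938, and the adjusted p = 0.0605, 0.0559 and 0.0559 with an estimated correlation. Against day 0 RPL5, SF3B3 and PSMB3 stood at -2.08, -2.12 and -2.73 (medians), so their guides were lost less than in DMSO rather than gained. Cell-cycle drivers shifted up without a passing member (median 0.64, camera adjusted p = 0.0400, and adjusted p = 0.137 with an estimated correlation). Lysine demethylases, with KDM5B and KDM6A down (2 of 23), and other methyltransferases, with NSD1, SETD3 and SETD5 down (3 of 22), lay below the other genes rather than far below 0. Their medians were -0.05 and -0.08 (camera adjusted p = 0.0272 for both, and adjusted p = 0.099 for both with an estimated correlation). Scaling on control guides raised the median of all genes from 0.09 to 0.22, so the sign of these last medians depends on the scaling.

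Other lists in MED23 knockout cells held passing members without a shift of the whole. BAF and PBAF remodellers had 5 of 21 members up, among them the ATPase SMARCA4 (1.95), SMARCD1 (2.28) and DPF2 (1.40, medians, camera adjusted p = 0.203). MLL methyltransferase subunits had 5 up and 1 down of 20, with WDR5 (1.93) and WDR82 (2.24) up (camera adjusted p = 0.203). Against day 0 WDR5 and WDR82 stood at -1.13 and -1.37 (medians). Polycomb repressive complex members EED (1.49), EZH2 (0.87) and RBBP4 (2.47) rose and RBBP7 fell (-0.56, camera adjusted p = 0.449). Cullin ligase genes rose for CUL5 (1.61) and CUL2 (1.71) and fell for CUL4B (-0.38) and FBXW7, which degrades MYC and cyclin E (-0.76, camera adjusted p = 0.335). The acetyltransferase CREBBP (2.06), the cell-cycle brake RB1 (1.66) and SMAD4 (1.15) also rose. So did the RNA methyltransferase pair METTL3 (1.85) and METTL14 (1.91), which were chosen outside the naming rule after the values were seen. Of these risen genes, SMARCD1, EED, CUL5, RB1 and SMAD4 were enriched against day 0 as well. Besides WDR5 and WDR82, those not called against day 0 were CUL2 (-0.28), DPF2 (-0.22), METTL3 (0.11), CREBBP (0.27), RBBP4 (0.29), METTL14 (0.54), EZH2 (0.62) and SMARCA4 (0.84, medians). SETDB1 did not pass in MED23 knockout cells (median -0.26, edgeR/RRA adjusted p = 0.696).

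Of the 86 genes enriched by vemurafenib in MED23 knockout cells, 47 were also depleted in DMSO, where 10.9 would overlap between independent lists. In 20 simulated tables without effects the overlap was 0 genes at most. Such tables leave few or no genes to be called in either list, so they cannot show how much overlap the shared DMSO libraries create. These 47 had a median log2 fold change of -0.88 between vemurafenib at day 14 and day 0, and 2 of them, TADA2B (3.93) and CCDC101 (2.10), were enriched against day 0. The other 39 had a median of 1.02 against day 0, and 24 of them were enriched. CUL3 stood at 8.77 against day 0, NF1 at 6.40 and MED12 at 4.31, while CTRL guides stood at 1.00 (medians). The 3 DMSO libraries are too few to leave 2 in each part of a split, so part of the overlap may come from shared controls.

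**Figure D1:**
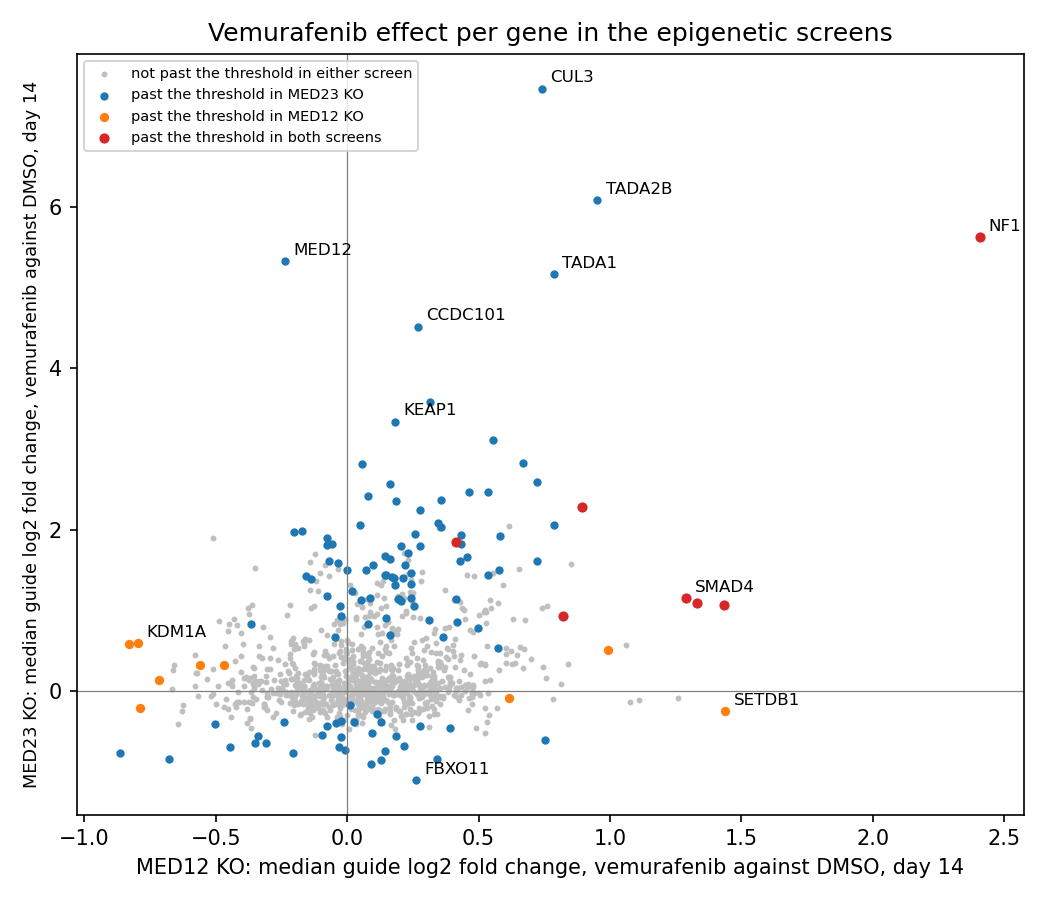
Median log2 fold change over 10 guides of vemurafenib against DMSO at day 14 in MED12 knockout cells (x axis) and MED23 knockout cells (y axis), 1 point per gene, with genes past the threshold in orange (MED12 knockout), blue (MED23 knockout), red (both) or grey (neither). CUL3 lay at 0.74 and 7.47, whereas SETDB1 lay at 1.44 and -0.26.

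The drug response differed between the knockouts when both epigenetic screens were fitted together. The vemurafenib effect in MED12 knockout cells minus that in MED23 knockout cells was -6.78 for CUL3 (median over 10 guides of the log2 difference), -5.55 for MED12, -5.08 for TADA2B, -4.19 for TADA1, -3.44 for CCDC101, -2.99 for KEAP1 and -2.39 for NF1 (edgeR/RRA adjusted p = 2.79e-05 for each). The mean over guides was -5.92 ± 0.68 for CUL3, -5.05 ± 0.27 for TADA2B and -2.51 ± 0.45 for NF1 (SE over 10 guides). TAF6L and MED19 differed by -2.84 and -2.34 (edgeR/RRA adjusted p = 0.000134 for both), and NF2 by -2.28 (adjusted p = 0.00203). SETDB1 was the gene among the 10 with the lowest adjusted p whose effect was higher in MED12 knockout cells, by 1.94 (edgeR/RRA adjusted p = 2.79e-05). KDM1A was lower in MED12 knockout cells (-1.20, edgeR/RRA adjusted p = 0.000624), while BRAF did not pass (-1.03, adjusted p = 0.425). In all 47 genes differed, 12 higher and 35 lower in MED12 knockout cells. The count was 28, 29, 30, 30, 24 and 30 without MED12 knockout DMSO libraries 1 and 3, vemurafenib libraries 1, 2 and 3 and MED23 knockout DMSO library 2. Dose differed between the knockouts (2 µM against 1 µM) and each knockout is a separate screen, so genotype, dose and screen cannot be told apart.

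Vemurafenib enriched 7 genes in both knockouts, among them METTL3, NF1, SMAD4, SMARCD1 and TP53BP1, where 0.771 would be shared by chance (Fisher p = 1.27e-06). No depleted gene was shared, where 0.167 was expected. For growth, 8 enriched genes were shared (1.72 expected, Fisher p = 0.000166), among them RB1, the checkpoint kinase CHEK2 and the remodeller CHD8, and 13 depleted genes (3.41 expected, Fisher p = 5.20e-06).

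During growth in DMSO, MED12 knockout cells gained guides against MPHOSPH8, a subunit of the HUSH silencing complex, from 929 ± 42.9 to 4361 ± 917 CPM over 14 days (gene score change 1.79 ± 0.23). The cell-cycle repressor RB1 rose by 1.49 ± 0.18, TP53BP1 by 1.56 ± 0.11 and CHEK2 by 0.97 ± 0.09 (edgeR/RRA adjusted p = 4.46e-05 for each). SMARCA4 rose by 1.62 ± 0.10 and SETDB1 by 1.55 ± 0.08 (edgeR/RRA adjusted p = 5.57e-05 for both), and the cyclin-dependent kinase inhibitor CDKN1A by 1.18 ± 0.14 (adjusted p = 0.000201). Its relative CDKN1B rose by 1.10 ± 0.19 and SMARCC1 by 1.41 ± 0.11 (edgeR/RRA adjusted p = 0.000343 for both). NF2 rose by 1.03 ± 0.12 (edgeR/RRA adjusted p = 0.0486). Guides fell for WDR5, a scaffold of histone methyltransferases (-2.26 ± 0.09, edgeR/RRA adjusted p = 0.000198). They also fell for ELP3, the catalytic subunit of Elongator (-2.26 ± 0.17, edgeR/RRA adjusted p = 0.000324), and for EZH2, the methyltransferase of Polycomb (-1.65 ± 0.32, adjusted p = 0.000966). So did TADA2A of ATAC (median -1.04, edgeR/RRA adjusted p = 0.000986), the histone chaperone RBBP4 (-1.68 ± 0.19, adjusted p = 0.00124) and the DNA methylation factor UHRF1 (-1.49 ± 0.31, adjusted p = 0.00567). Others were the centromeric histone CENPA (-1.70 ± 0.25, edgeR/RRA adjusted p = 0.00987) and RNF8, a ubiquitin ligase of the DNA-damage response (-1.41 ± 0.20, adjusted p = 0.0116). BRAF did not pass (-1.42 ± 0.18, edgeR/RRA adjusted p = 0.237). In all 31 genes rose and 27 fell (62 fell with the block), against 180 at an unadjusted p under 0.05 with 55.8 expected, and 20 rose without DMSO library 3 of day 14.

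The lists for growth in MED12 knockout cells paired a gain for checkpoint and cell-cycle brakes with losses for core machines. Brakes rose for 7 of 15 members (9 up and 1 down over the list alone, median 0.80, camera adjusted p = 4.06e-05, and adjusted p = 0.0164 with an estimated correlation). BAF and PBAF remodellers rose for 4 of 21, ARID2, SMARCA4, SMARCC1 and SMARCD1 (5 over the list alone, median 0.50, camera adjusted p = 0.00254, and adjusted p = 0.0963 with an estimated correlation). Ribosomal proteins fell, with RPL13 (-1.90) and RPS15A (-1.43) past the threshold (2 of 37, 4 over the list alone, median -0.84, camera adjusted p = 1.63e-08, and adjusted p = 0.0259 with an estimated correlation). Spliceosome factors fell as a list (median -0.63, camera adjusted p = 0.00254, and adjusted p = 0.0346 with an estimated correlation). Lists that fell with the preset correlation only were the proteasome (-0.82), RNA polymerases (-0.38), replication (-0.31), histone chaperones (-0.44), INO80-type remodellers (-0.34), MLL methyltransferases (-0.33), cell-cycle drivers (-0.49) and SAGA with ATAC (-0.21, medians). In that order their camera adjusted p values were 0.00576, 0.00321, 0.0174, 0.0174, 0.0244, 0.0113, 0.0309 and 0.0387, and the adjusted p = 0.0515, 0.115, 0.064, 0.0589, 0.0589, 0.0515, 0.076 and 0.0759 with an estimated correlation. The call for SAGA was also lost with the block (camera adjusted p = 0.0645). Among them TADA2A, TRRAP and WDR5 of SAGA and ATAC fell as genes, as did PSMB3 of the proteasome and RBBP4 of the chaperones. Polycomb members EED, EZH2 and RBBP4 fell as genes while the list had a median of 0.37 and a mean of -0.25 and did not shift (camera adjusted p = 0.82). Growth changes are relative to the scaling: control guides moved the median of all genes from 0.15 to -0.15 in MED12 knockout and from 0.06 to -0.51 in MED23 knockout cells.

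Growth of MED23 knockout cells selected against core machines. The ribosomal protein RPL5 fell from 749 ± 1.24 to 73.1 ± 9.72 CPM (gene score change -3.62 ± 0.06), and guides fell for PPP2CA, the catalytic subunit of phosphatase PP2A (-3.40 ± 0.16, edgeR/RRA adjusted p = 8.92e-05 for both). RUVBL2, an ATPase of chromatin and chaperone complexes (-2.84 ± 0.18, edgeR/RRA adjusted p = 0.000251), the nuclear import receptor KPNB1 (-3.56 ± 0.16, adjusted p = 0.000297), TRRAP (-3.23 ± 0.05, adjusted p = 0.000365) and the hydroxylase KDM8 (-1.65 ± 0.12, adjusted p = 0.000478) fell. Ribosomal proteins that fell were RPL27 (-2.96 ± 0.06, edgeR/RRA adjusted p = 0.000312) and RPS9 (-3.37 ± 0.18, adjusted p = 0.000607). MAP2K1 (median -3.38), the cyclin CCND1 (-2.58), the arginine methyltransferases PRMT1 (-2.96) and PRMT5 (-2.55) and the regulator MDM4 (-2.71) fell too. CHD8 rose by 1.04 ± 0.03 and TSC1 by 0.78 ± 0.03 (edgeR/RRA adjusted p = 8.92e-05 for both), and METTL8, an RNA methyltransferase, by 0.75 ± 0.04 (adjusted p = 0.000111). The deubiquitinase CYLD, which restrains NF-kappa-B, rose by 1.18 ± 0.07 (edgeR/RRA adjusted p = 0.000191). TBL1XR1, a corepressor subunit, rose by 0.93 ± 0.08 and CHEK2 by 0.88 ± 0.04 (edgeR/RRA adjusted p = 0.000607 for both). The ribosomal RNA methyltransferase METTL5 rose by 0.75 ± 0.10 (edgeR/RRA adjusted p = 0.00151) and DYRK1A by 0.70 ± 0.03 (adjusted p = 0.00156). In total 62 genes rose and 141 fell, against 308 at an unadjusted p under 0.05 with 55.8 expected. Control guides rose as well (median log2 fold change 1.21 for CTRL, 1.17 for Zhang and 0.423 for AAVS1). The rises named here are relative to all genes and do not show a gain over CTRL or Zhang guides.

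Ribosomal proteins fell for 29 of 37 members in MED23 knockout cells (33 over the list alone, median -2.98), spliceosome factors for 11 of 15 (14 alone, -2.40), proteasome subunits for 5 of 10 (7 alone, -2.65) and RNA polymerase subunits for 5 of 10 (8 alone, -1.62). The camera adjusted p values were 3.4e-12, 1.31e-06, 0.000223 and 0.000367, and each list kept its call with an estimated correlation (adjusted p = 0.043 for the ribosome). Cell-cycle drivers (3 of 10, median -1.97, camera adjusted p = 0.00217, and adjusted p = 0.0609 with an estimated correlation) fell with CCND1 and its partner CDK6 (-2.09). SAGA and ATAC subunits fell with TADA2B (-1.96) and CCDC101 (-2.44, 5 down and 1 up of 26, median -0.88, camera adjusted p = 0.00495, and adjusted p = 0.0609 with an estimated correlation). Replication (4 of 7, -1.42), MLL methyltransferase (5 of 20, -0.71) and INO80-type lists (4 of 30, -0.58) fell with the preset correlation alone (camera adjusted p = 0.00366, 0.0112 and 0.0322, and adjusted p = 0.198, 0.124 and 0.124 with an estimated correlation). Checkpoint and cell-cycle brakes rose for 8 and fell for 1 of 15 (median 0.85, camera adjusted p = 0.00255, and adjusted p = 0.0829 with an estimated correlation), with CDKN2A (0.94), RB1 (1.13) and FBXW7 (0.99) among those up. These values lay below the median of CTRL guides (1.21).

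Core essential genes were compared with the other genes in each library. In MED23 knockout cells the median gene score of 79 core genes relative to the others was 0.01 ± 0.01 at day 0 (SD, n = 3 libraries), -2.58 ± 0.02 after 14 days in DMSO and -1.71 ± 0.06 in vemurafenib. In MED12 knockout cells it was already -0.94 ± 0.01 at day 0, -1.89 ± 0.07 in DMSO and -1.92 ± 0.13 in vemurafenib. With 202 core genes of the whole-genome library the values were -1.19 ± 0.06, -2.01 ± 0.01 and -1.93 ± 0.10. The difference between vemurafenib and DMSO was 0.87 in MED23 knockout cells, -0.03 in MED12 knockout cells and 0.07 in the whole-genome screen (exact permutation p = 0.1, 1 and 0.3, where 0.1 is the smallest value possible).

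**Figure D2:**
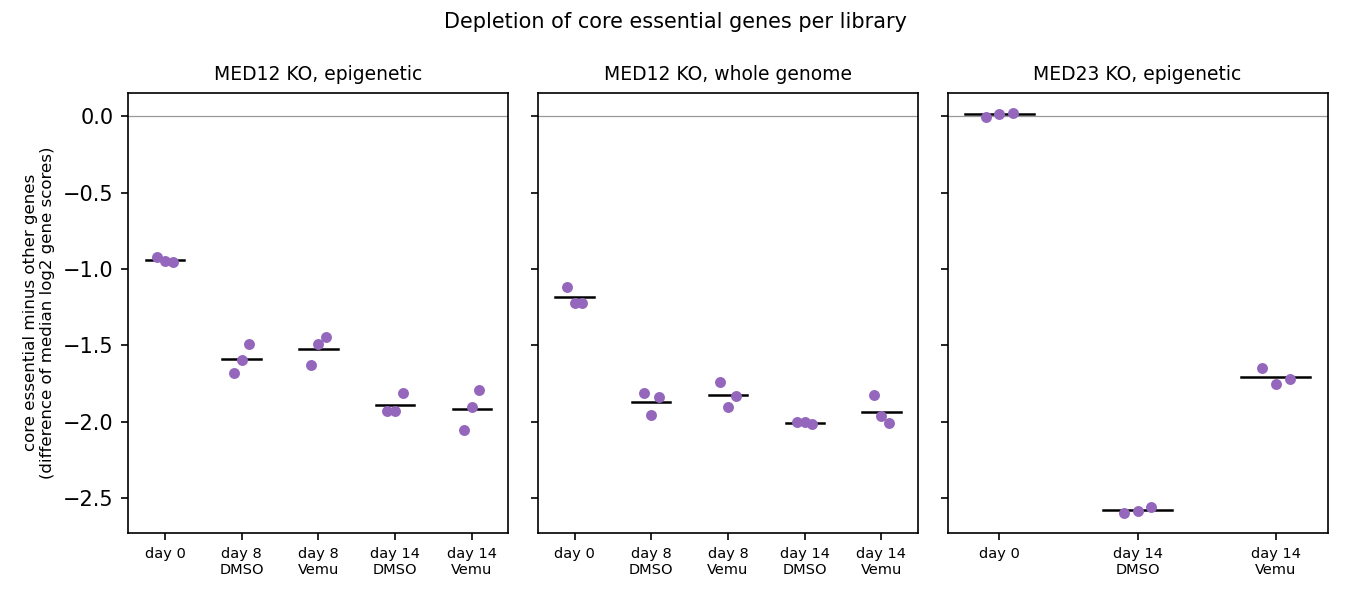
Median gene score of core essential genes minus that of other genes (log2 CPM, y axis) in each group (x axis) for the epigenetic screens of MED12 and MED23 knockout cells and the whole-genome screen, with 1 point per library and the group mean as a black line. Core genes stood at -0.94 at day 0 in MED12 knockout cells and at 0.01 in MED23 knockout cells.

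In the whole-genome screen of MED12 knockout cells at day 14 of vemurafenib edgeR/RRA called 0 of 19101 genes, against 1006 at an unadjusted p under 0.05 with 955 expected. Median-ratio and control-guide scaling, no filter, DESeq2 guide ranks and gene sums also called 0, the block called 1 gene in each direction, and a fit to the compared groups alone called 1 depleted gene. Leaving out DMSO library 2 or vemurafenib library 1 gave 1 gene in each direction. GRB2, the adaptor between receptor kinases and RAS, stood lowest in p among depleted genes: its summed guides were at 9.41 ± 6.55 CPM in vemurafenib and 75.9 ± 36.0 in DMSO (gene score change -2.59 ± 0.20), without passing (edgeR/RRA adjusted p = 0.0955, and 0.0439 with the block, range 0.00712 to 0.979). MEN1 (-1.12 ± 0.31, edgeR/RRA adjusted p = 0.134) and C11orf21 (adjusted p = 0.361) did not pass either. Nor did the RNA-binding proteins RBM12 (1.57 ± 0.51, edgeR/RRA adjusted p = 0.111, and 0.0439 with the block, range 0.0401 to 0.979) and ELAVL1 (1.33 ± 0.62, adjusted p = 0.111), or the nucleolar protein RRP1 (0.61 ± 0.22, adjusted p = 0.134). NF1 did not pass at either day (1.06 ± 0.22 at day 8 and a median of 2.55 at day 14, edgeR/RRA adjusted p = 0.378 and 0.503), nor did NF2 at day 14 (1.15 ± 0.36, adjusted p = 0.653).

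At day 8 of vemurafenib GRB2 fell in the whole-genome screen, from 40.0 ± 14.6 to 12.4 ± 2.84 CPM (-1.50 ± 0.42, edgeR/RRA adjusted p = 0.0258, and 0.0115 with the block, range 0.0115 to 1). B4GALT7, which starts proteoglycan side chains, fell as well, a call lost with the block (-0.76 ± 0.29, edgeR/RRA adjusted p = 0.0321, and 0.185 with the block, range 0.0248 to 1). PEA15, a cytoplasmic anchor of ERK, rose from 3.48 ± 1.83 to 13.7 ± 3.74 CPM (1.19 ± 0.32, edgeR/RRA adjusted p = 0.0258, and 0.218 with the block, range 0.00378 to 1). ELAVL1, which stabilizes messenger RNAs, rose by 0.78 ± 0.27 (edgeR/RRA adjusted p = 0.0248, and 0.0554 with the block, range 0.00567 to 1). In all 2 genes rose and 3 fell, against 1075 at an unadjusted p under 0.05 with 955 expected. With the block edgeR/RRA called 0 enriched genes, against 573 at an unadjusted p under 0.05, and 1 depleted gene. Enriched genes numbered 1 without DMSO library 1, depleted genes 1 without DMSO library 1 or 2, and edgeR/RRA called 0 without any other library of day 8. Core MAPK genes shifted down at day 8 (31 measured, 1 fell, GRB2, median -0.06, camera adjusted p = 0.000324, and adjusted p = 0.0216 with an estimated correlation). Over the list alone 5 fell and 1 rose, namely the adaptors GRB2 and SHC1, the phosphatase PTPN11, the RAS scaffold SHOC2 and the transcription factor JUN down and the adaptor GAB1 up. Mitochondrial respiration and ribosome genes (COX4I1 alone past its list, median 0.17, camera adjusted p = 0.000151, and adjusted p = 0.0216 with an estimated correlation) shifted up. So did ribosomal proteins (median 0.17, 3 past the list alone, camera adjusted p = 0.0138, and adjusted p = 0.0264 with an estimated correlation). Resistance genes, with NF1 and SPRED1, a partner of NF1, past the list alone (median 0.16), SAGA and ATAC (0.25) and replication genes (0.19) did so with the preset correlation only. Their camera adjusted p values were 0.00466, 0.0163 and 0.0467, and the adjusted p = 0.0856 for each with an estimated correlation. Core essential genes had fallen from day 0 relative to other genes in both arms (gene score -0.68 in DMSO and -0.64 in vemurafenib). The shifts of ribosomal proteins and replication genes against DMSO therefore do not show a gain from day 0. The 6 lists became 1, 2, 2, 3 and 2 without DMSO libraries 1, 2 and 3 and vemurafenib libraries 1 and 3, and camera called 0 without vemurafenib library 2.

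At day 14 respiration and mitochondrial ribosome genes shifted up in the whole-genome screen without a passing member (64 measured, median 0.55, camera adjusted p = 0.000746, and adjusted p = 0.0482 with an estimated correlation). The same list fell during growth in DMSO, so this shift against DMSO does not show a gain from day 0. Resistance genes (median 0.18), with NF1, NF2 and SPRED2 past the list alone, and checkpoint and cell-cycle brakes (0.47) shifted with the preset correlation only (camera adjusted p = 0.0105 for both, and adjusted p = 0.144 for both with an estimated correlation). Without DMSO library 3 camera called 1 list, and without DMSO library 1 or vemurafenib library 2 it called 0. Median-ratio scaling raised the median of all genes from 0.06 to 0.21 at day 14 and called 5 lists. Between days 8 and 14 edgeR/RRA called 0 genes, against 1023 at an unadjusted p under 0.05 with 955 expected, as did DESeq2 guide ranks, gene sums and the block, and 1 gene was called without DMSO library 2 at day 14. TWNK, the mitochondrial DNA helicase, stood lowest in p there and did not pass (median difference 2.97, edgeR/RRA adjusted p = 0.523). A list of MED12, MED23, BRAF, NF1 and NF2 shifted up between the days (medians over guides -0.08, 0.23, 1.45, 1.31 and 1.53 in that order). The checkpoint and cell-cycle brakes (list median 0.37) did so too (camera adjusted p = 0.0124 for both lists, and adjusted p = 0.153 for both with an estimated correlation).

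Growth of MED12 knockout cells in the whole-genome screen raised RBM15, an adaptor of RNA methylation, from 53.7 ± 15.1 to 914 ± 423 CPM (3.87 ± 0.45, edgeR/RRA adjusted p = 0.00255). MORC2, an ATPase that works with the HUSH silencing complex, rose from 29.5 ± 8.46 to 403 ± 189 CPM (3.13 ± 0.41, edgeR/RRA adjusted p = 0.0135). KIRREL1, a membrane activator of the Hippo pathway, rose by 2.31 ± 0.50 (edgeR/RRA adjusted p = 0.0106), and UBE2F, a conjugating enzyme that activates CUL5, by 1.74 ± 0.43 (adjusted p = 0.0161). Many guides of depleted genes were near 0 reads after growth, so no fold is given for them. TWNK went from 39.2 ± 4.71 to 0.738 ± 0.491 CPM (gene score change with 0.5 added -3.83 ± 0.12), and MOCS3, which thiolates transfer RNAs, from 10.2 ± 2.14 to 0.0198 ± 0.00198 (-2.43 ± 0.09, edgeR/RRA adjusted p = 0.00255 for both). ELOB, a subunit of CUL2 and CUL5 ligases, fell (-2.56 ± 0.15, edgeR/RRA adjusted p = 0.00287), and so did TERT, the telomerase catalytic subunit (-2.16 ± 0.37, adjusted p = 0.00828). The remaining 6 named genes lost their edgeR/RRA call with the block, while gene sums with edgeR and the block called each of them depleted. Among them was the glycolytic enzyme GAPDH (-1.98 ± 0.03, edgeR/RRA adjusted p = 0.00535, and 0.084 with the block, range 0.00525 to 0.084). Next were the mitochondrial iron carrier SLC25A28 (-1.99 ± 0.11, edgeR/RRA adjusted p = 0.00573, and 0.0654 with the block, range 0.00573 to 0.0654) and the ATPase RUVBL1 (-1.66 ± 0.08, adjusted p = 0.00573, and 0.0743 with the block, range 0.00191 to 0.113). The others were RPL27 (-1.39 ± 0.03, edgeR/RRA adjusted p = 0.00573, and 0.128 with the block, range 0.00191 to 0.137) and the polymerase assembly factor GPN2 (-2.06 ± 0.10, adjusted p = 0.00679, and 0.0798 with the block, range 0.00541 to 0.111). The last was the spindle checkpoint protein BUB3 (-1.54 ± 0.10, edgeR/RRA adjusted p = 0.00799, and 0.192 with the block, range 0.00541 to 0.254). BRAF (adjusted p = 0.804 from edgeR/RRA) and NF2 (1.89 ± 0.19, adjusted p = 0.309) did not pass. In all 6 genes rose and 23 fell, against 1471 at an unadjusted p under 0.05 with 955 expected. Enriched genes numbered 3 without DMSO library 3 of day 14, and depleted genes 10 and 7 without DMSO libraries 1 and 3. Control guides moved the median of all genes from 0.30 to -0.37 for growth.

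Lists made the whole-genome growth pattern clearer than single genes did, with the median gene score change of a list set against -0.21 for all other genes. Ribosomal proteins fell to -1.01 (71 tested of 72 measured, 2 fell, 12 over the list alone, camera adjusted p = 6.28e-05 with an estimated correlation). Under the same test replication genes fell to -1.22 (camera adjusted p = 0.000435), the spliceosome to -1.11 (adjusted p = 0.00327), RNA polymerases to -1.03 (adjusted p = 0.00334) and the proteasome to -1.01 (adjusted p = 0.0012). Respiration and mitochondrial ribosome genes fell to -0.97 (camera adjusted p = 0.00327 with an estimated correlation), protein arginine methyltransferases to -1.07 (adjusted p = 0.0274) and the head and middle modules of Mediator to -0.89 (20 measured, adjusted p = 0.00789). Checkpoint and cell-cycle brakes rose, at 0.33 (1 of 19, and 5 up and 1 down over the list alone, camera adjusted p = 0.00876 with an estimated correlation). Hippo pathway genes rose relative to other genes, with KIRREL1 past all genes and 5 up and 1 down over the list alone, among them NF2, PTPN14 and WWC1 (camera adjusted p = 0.0213 with an estimated correlation). The kinase module of Mediator, to which MED12 belongs, did not shift (6 measured, camera adjusted p = 0.507). Acetyltransferases (-0.77), histone chaperones (-0.79) and INO80-type remodellers (-0.51) fell as well (camera adjusted p = 0.00793, 0.0225 and 0.0296 with an estimated correlation). Cell-cycle drivers, cohesin, ferroptosis and histone ubiquitin lists passed with the preset correlation only (camera adjusted p = 0.0356, 0.0157, 0.0256 and 0.0354, and adjusted p = 0.0599, 0.0949, 0.0528 and 0.0599 with an estimated correlation). The call for cell-cycle drivers was lost with the block as well (camera adjusted p = 0.127).

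Growth effects in the epigenetic and whole-genome libraries of MED12 knockout cells correlated across 1089 shared genes (Spearman 0.522, bootstrap interval 0.476 to 0.564, Pearson 0.518), and vemurafenib effects at day 14 did so less (Spearman 0.109, interval 0.0498 to 0.164, Pearson 0.193). With gene scores, an alternative chosen after the result was seen, the latter was 0.246 (Pearson 0.361). Of the genes enriched by vemurafenib in the epigenetic library, 9 of 10 lay on the same side in the whole-genome library, and 4 of them, with NF1, SETDB1 and TP53BP1, had an unadjusted p under 0.05 there (0.404 expected, Fisher p = 0.000409). All 6 depleted genes lay on the same side, BPTF with an unadjusted p under 0.05 (0.209 expected, Fisher p = 0.192). At day 8 an unadjusted p under 0.05 was met by 3 of 12 enriched genes, among them NF1 and SETDB1 (0.672 expected, Fisher p = 0.0256). For that day CDK2, EGFR, KMT2D, MEN1 and SMARCC1 were the depleted genes with an unadjusted p under 0.05 in the whole-genome library (Fisher p = 5.34e-06). For growth 25 of 30 enriched and 26 of 27 depleted genes lay on the same side, and TERT passed in both libraries.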

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

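The tests on genes also depleted in DMSO, on the guides with most reads and on exchanged group labels were chosen after the result was seen; the test on genes not depleted in DMSO and both tests on day 0 were fixed before it.

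Drug effects that differed between days, knockouts or doses were marked for a closer look, each by its interaction test. In MED12 knockout cells 6 genes had a larger vemurafenib effect at day 14 than at day 8, among them NF1 (median difference 1.39), TP53BP1 (0.78), SMAD4 (0.80), METTL3 (0.17) and SETDB1 (0.65). Between MED12 and MED23 knockout cells 47 genes differed at day 14, with CUL3 (-6.78), MED12 (-5.55), TADA2B (-5.08), TADA1 (-4.19), CCDC101 (-3.44), KEAP1 (-2.99), NF1 (-2.39), TAF6L (-2.84) and MED19 (-2.34) lower and SETDB1 (1.94) higher in MED12 knockout cells. Exchanged labels did not decide on chance for either number, since an exchange within 1 treatment or knockout leaves the day effect or drug effect of the other in the difference. Of 100 splits 14 gave 6 or more genes between the days (highest other 26, where the effects add, and 19 without that exchange) and 6 gave 47 or more between the knockouts (highest other 67, and 63 without it), the real split included, a number of splits raised from 25 after those had been seen.

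Genes enriched by vemurafenib in MED23 knockout cells may in part be genes whose loss slows growth, which would be lost less in cells that divide fewer times under the drug. For the 47 that were also depleted in DMSO the median was what such an account needs, -0.88 in log2 against day 0, although 15 were called depleted and 2 enriched against day 0 and 5 stood above it. Of the other 39, 61.5%, among them CUL3, NF1 and MED12, were enriched against day 0. This share and the median of the 47 follow in part from the split, since the change against day 0 combines the drug and growth changes. Neither value therefore decides on the account. Without the split, 26 of the 86 were enriched against day 0 and 15 depleted. Control guides also stood above day 0 in vemurafenib (medians 1.00 for CTRL, 0.957 for Zhang and 0.317 for AAVS1). Some of the 26 lay below CTRL guides, such as TP53BP1 (0.82) and SMARCD1 (0.89). A place above day 0 therefore does not decide on the account for the 26. CUL3, NF1 and MED12 stood at 8.77, 6.40 and 4.31, far above the control guides. Fewer divisions alone would not give this, which argues against the account for these genes only. The number of enriched genes did not rest on the 50 guides with most vemurafenib reads. Without them and with scaling on control guides 85 genes were enriched, 79 of them among the 86 (CUL3 not tested, NF2 not past). Guides are ranked against each other after scaling, so removing these guides could not show whether the reads they took affected calls from the other guides. Dose, genotype and screen stay open for both parts, since the design confounds them.

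Core essential genes stood lower at day 0 in MED12 than in MED23 knockout cells of the epigenetic screens, for 79 of 79 genes (difference -0.95), which may reflect selection before the day-0 sample. A library composition unrelated to growth was argued against by a Spearman correlation of 0.418 between the day-0 difference and growth in the whole-genome screen of MED12 knockout cells. Checkpoint and cell-cycle brakes stood higher at day 0 in MED12 knockout cells than other genes did, by a median of 0.351, as more selection would give, although 5 of 15 members stood lower. How many days passed between infection and day 0 is not given in the sources used here, and genotype as a biological explanation was not tested.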

How the results depend on the processing

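Tests on exchanged labels and the alternatives gene sums with the block, the block in the list test, gene scores for the comparison of libraries and removal of guides with most reads were chosen after the result was seen. No named gene that had been called reversed its direction in any alternative. The core essential difference between vemurafenib and DMSO in MED12 knockout cells, -0.03, ranged from -0.09 to 0.04 when 1 library was left out. Control-guide scaling moved the median of all genes in growth from 0.15 to -0.15 in MED12 knockout cells, from 0.06 to -0.51 in MED23 knockout cells and from 0.30 to -0.37 in the whole-genome screen. Named genes kept their side of the threshold in 1613 of 1853 gene and setting pairs and lost it in 240. The share lost differed between results: 35 of 56 at day 8 of the whole-genome screen, 68 of 208 at day 8 of MED12 knockout cells and 1 of 273 in growth of MED23 knockout cells. The cause was not tested where a count moved, apart from fewer libraries in a fit. In the whole-genome screen at day 14 of vemurafenib the median guide had 110 to 155 reads and 7338 to 7939 guides had none, and whether this lowered its number of calls was not tested. In simulated data from that screen 0% of 2-fold and 10% of 4-fold changes were recovered, so the lack of calls does not show that such changes were absent. At day 8 in MED12 knockout cells TRIM28, MEN1 and NTMT1 each passed in 6 of 13 alternatives, CDK2, EGFR and KMT2D in 8 and SMARCC1 and SMARCD1 in 9. At day 14 BPTF passed in 7, CDK2 in 8 and MAP3K1 in 10 of 13, in growth NF2 in 9 and RNF8 in 10 of 13, and in whole-genome growth TERT and UBE2F in 9 of 14.

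With the replicate block, the count in MED12 knockout cells was 17 depleted at day 8, 62 depleted in growth and 12 between days, and in the whole-genome screen edgeR/RRA called 0 enriched and 1 depleted at day 8 and 1 and 1 at day 14. METTL17 lost its call at day 14 in MED12 knockout cells with the block. In both MED12 screens the block changed no other call of a gene or list named as rising or falling than those given beside the results. In MED23 knockout cells numbers did not pair all libraries (r = -0.188 to 0.343 for the same number). As a hint from the data, DMSO libraries 1 and 2 correlated with numbers 2 and 1 of the other groups (r = 0.283 to 0.343), while other libraries correlated above 0 with their own number alone. The block by number is therefore no paired fit there, and it gave 97 enriched and 35 depleted genes for vemurafenib and 63 and 143 for growth. Gene sums with edgeR gave 0 and 0 in MED12 knockout cells at day 8, 17 enriched at day 14, 51 and 63 in growth and 0 between days, 206 and 68 for vemurafenib and 200 and 339 for growth in MED23 knockout cells, and 0 and 0 at day 8 and 2 and 5 in growth in the whole-genome screen. With the block as well, gene sums gave 0 and 0 at day 8 and 326 and 577 in growth there. At an unadjusted p under 0.05 gene sums with edgeR held 14 genes at day 8 and 20 between days in MED12 knockout cells, and 5 at day 8 of the whole-genome screen, or 22 with the block. A fit to the compared groups gave 14 depleted at day 8 in MED12 knockout cells, and 1 depleted at day 8, 1 at day 14 and 37 in growth in the whole-genome screen. DESeq2 ranks gave 12 depleted in whole-genome growth and control-guide scaling 15.

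With the estimated correlation camera called 0, 0 and 3 lists for days 8, 14 and growth in MED12 knockout cells, 2 and 4 for vemurafenib and growth in MED23 knockout cells, and 3 and 1 at days 8 and 14 in the whole-genome screen. Where it called 0, at days 8 and 14 in MED12 knockout cells, 7 and 6 lists had an unadjusted p under 0.05. Without core essential lists it called 7 in growth of MED12 knockout cells and 3 and 5 for vemurafenib and growth of MED23 knockout cells. Median-ratio and control-guide scaling each gave 5 lists at day 14 in the whole-genome screen. Scaling on control guides moved the core essential depletion in growth to -2.56 in MED23 knockout cells and to -0.68 in the whole-genome screen (-0.62 for vemurafenib against day 0). It moved the median difference between knockouts over all genes from 0.11 to -0.26, and median-ratio scaling moved the median difference between days in the whole-genome screen from 0.05 to 0.21. The Spearman correlation between libraries was 0.246 for vemurafenib and 0.577 for growth with gene scores, and 0.565 for growth with means.

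Leaving out 1 library at a time gave these ranges of enriched and depleted genes: in MED12 knockout cells 6 to 9 and 1 to 5 at day 8, 6 to 9 and 2 to 3 at day 14, 20 to 33 and 21 to 32 in growth and 3 to 7 between days. In MED23 knockout cells they were 70 to 91 and 26 to 34 for vemurafenib and 48 to 62 and 125 to 146 for growth. In the whole-genome screen edgeR/RRA called 0 to 1 and 0 to 1 at day 8, 0 to 1 and 0 to 1 at day 14, 0 to 1 between days and 3 to 7 and 7 to 32 in growth. Between knockouts 24 to 41 genes differed. Lists called by camera ranged from 0 to 7, 0 to 4 and 11 to 12 in MED12 knockout cells, 7 to 10 and 10 to 10 in MED23 knockout cells, and 0 to 3, 0 to 2 and 12 to 17 in the whole-genome screen.

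For the 10 ways of splitting 3 against 3, the splits are too few for a share under 0.05. The real split gave 12 and 7 genes at day 8 of MED12 knockout cells (highest other 2 and 1), 10 and 6 at day 14 (1 and 0) and 31 and 27 in growth (1 and 2). It gave 86 and 31 for vemurafenib in MED23 knockout cells (1 and 1) and 62 and 141 in growth (1 and 5), and for each of these 1 of 10 splits, the real one, reached that number. In the whole-genome screen it gave 2 and 3 at day 8 (highest other 3 and 2, with 4 of 10 splits reaching 2 enriched), 6 and 23 in growth (0 and 0), and edgeR/RRA called 0 in all 10 of 10 splits at day 14. Between its days all 25 of 25 splits reached the 0 genes that edgeR/RRA called, with a highest other of 4, where the exchange adds the effects, and of 1 without it. These exchanges do not decide on chance, since they leave the day effect of 1 treatment in the difference. Lists numbered 7, 4 and 12 in MED12 knockout cells (highest other 1, 0 and 5), 9 and 10 in MED23 knockout cells (3 and 9), and 6, 3 and 17 in the whole-genome screen (0, 0 and 6).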

Other observations

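All tests on control guides in this part were chosen after the result was seen, as were the difference in growth between the knockouts and the silencing genes named outside the fixed rule.

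Single genes of chromatin silencing, but not the fixed list, were gained during growth of MED12 knockout cells. MPHOSPH8 and SETDB1 rose in the epigenetic library (medians 2.13 and 2.09, edgeR/RRA adjusted p = 4.46e-05 and 5.57e-05), and MORC2 rose in the whole-genome library (3.42, adjusted p = 0.0135). In the whole-genome library SETDB1 (2.75), its partner ATF7IP (2.09), MPHOSPH8 (1.80) and the HUSH subunit PPHLN1 (2.06) had positive medians without passing (edgeR/RRA adjusted p = 0.586, 0.395, 0.258 and 0.2997). Gene sums with edgeR and the block called SETDB1, ATF7IP, PPHLN1 and FAM208A enriched there and TRIM28 depleted, and did not call MPHOSPH8. The fixed list of silencing factors had 1 member past the threshold there, 5 over the list alone, and did not pass as a list in that library or in the epigenetic one (camera adjusted p = 0.345 and 0.42, median log2 fold change 0.22 and -0.22).

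Growth differed between the knockouts for 44 genes that were higher and 22 that were lower in MED12 than in MED23 knockout cells. SETDB1 (2.36), TADA2B (2.32), MAP2K1 (2.87), PPP2CA (2.40) and TP53BP1 (1.66) were higher and PRMT3 (-1.68) lower (edgeR/RRA adjusted p = 0.000223, 0.000573, 0.000573, 0.000446, 0.000573 and 0.000223). Core genes differed between the knockouts at day 0 already, so growth from day 0 was counted from different starting levels.

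A cost of a DNA cut may separate guides that cut from guides that do not, since cut cells can pause. After 14 days in DMSO AAVS1 guides, which cut, stood below CTRL guides in both knockouts. Abundance at day 0 did not account for this in MED23 knockout cells, where matching guides on it left 0.993 of the difference of 0.777, and could not be told in MED12 knockout cells, where it left 0.876 of a difference of 0.22 that ranged from -0.112 to 0.357 over libraries. In the whole-genome screen guides without a named target stood above guides of tissue-restricted genes by 0.661, but after matching on day-0 abundance the difference was -0.0220, as abundance would give. Abundance at day 0 may itself carry a cost of a cut paid before that sample, so which of the 2 lay behind the difference could not be decided.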
